A study of Homo sapiens with 11 samples.

How the data were processed

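The series holds 11 samples of human tumour tissue: 8 droplet libraries of single cells and 3 long-read samples of the TGCT tumours, which were not analysed here. The tissue was dissociated with a Miltenyi kit and the libraries were made with the 10x 3' v3.1 chemistry, per the labels' protocols. The deposited values are raw UMI counts per gene and barcode with empty droplets included; the authors made them with Cell Ranger 4 per the file headers and with Cell Ranger 3.0 on GRCh38 per the submitters' processing notes, and which of these versions was used is not given in the sources used here, nor is the annotation. All libraries list the same 36601 features with gene symbols, of which 23076 were found in the reference table of gene names; genes are named by the symbols of the files.

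Tumours are the replicates, because titles with the same tumour number share a tumour: 3 TGCT against 2 GCTB, with the libraries of a tumour added together. Library totals ran from 47449399 to 115426451 UMIs. Barcodes were kept as cells with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs, and 39954 cells remained after doublet removal, at a median of 15132 UMIs in the deepest tumour (TGCT3) and 4858 in the shallowest (GCTB2). Other limits kept 43251 cells (500 UMIs and 250 genes), 36534 (2000 UMIs), 30058 (10% mitochondrial UMIs) and 27710 (a minimum per library from its largest barcodes). The study states 18788 cells. Doublets were scored with scrublet as implemented in scanpy 1.11.5, per library. Its automatic threshold marked 0 of 6411 cells in TGCT1's second library and had not worked, so the cells with the highest scores were removed at 0.8% per 1000 cells of a library (2.09% to 7%); this was chosen after the data were seen, and the automatic threshold is an alternative.

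Counts were scaled to 10000 per cell and log-transformed. Clusters were made from 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 1 (scanpy, igraph 0.11.9, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0), leaving out 47 ligand and receptor genes, sex-linked, immunoglobulin, T cell receptor, mitochondrial and ribosomal genes. 31 clusters were named from 14 marker lists by the mean scaled level of each list, over all markers of a class, and by their leading genes where several classes scored alike, which named cluster 1 macrophage although neutrophil markers scored higher; 10 stayed unnamed, where fewer than 3 markers were detected in 20% of the cells, where the 10 leading genes held more markers of another class, where several classes scored at 0.6 of the best or above and the leading genes did not decide or the UMIs exceeded 2 times the library's median, where UMIs were low and no marker led, or where an upper bound of free RNA exceeded 50% of the UMIs. The last limit, the profile of barcodes of 100 to 500 UMIs it rests on, and the details of the naming were set after the data were seen. 7 classes were named.

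UMIs were summed per tumour and class, with at least 20 cells of the class (the CSF1 sums had no minimum), and tested with edgeR 4.0.16 (R 4.3.3; filterByExpr, TMM, quasi-likelihood F test), with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 fold change is its absolute value over the square root of F. Mural-like and dendritic-like cells were compared as shares only. Shares were compared with an exact permutation test of the difference of means over the 10 splits of 5 tumours, whose smallest p is 0.1. Classes within TGCT, and stromal-like cells with 2 or more against 0 CSF1 UMIs, were compared with the tumour as a block; both classes come from the same tumours. For the CSF1 comparison each cell was thinned to 2000 UMIs, and CSF1 was left out. 22 fixed gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, in lists with at least 5 tested members, and again with an estimated correlation and with fry, which asks whether a list's genes move one way.

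The tests, lists, markers, filters, alternatives and the rule for named genes were chosen before the data were examined, with the exceptions given above and below. The rule takes, among genes past the threshold with at least 50 CPM in a group mean and no overlap between the tumour types, the 8 largest rises and 8 largest falls, filled up by unadjusted p where fewer passed. Markers, sex-linked, immunoglobulin, T cell receptor, ribosomal, mitochondrial and clone-named genes are not taken. To these it adds CSF1, CSF1R, TNFSF11, TNFRSF11A, TNFRSF11B and GFPT2 and up to 4 members of each gene list. For the CSF1 comparison it takes 10 rises and 6 falls with the same direction in all 3 TGCT tumours, filled up by unadjusted p, and for ligands and receptors the 8 with the lowest p beside CSF1, IL34, CSF1R, TNFSF11 and TNFRSF11A. After the data were seen, 1 endothelial-like gene was left unnamed because its level follows a person's haplotype. Genes with 1 to 3 UMIs in a group are given as the ratio of pooled CPM with a 95% counting interval, which covers counting error only.

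The edgeR steps were tested on simulated data, 1 set per comparison, with counts drawn from the real means, library sizes and dispersions and 200 genes changed by 2-, 4-, 8- or 16-fold. Of genes changed 4-fold and 16-fold, recovery was 28% and 76% for all-cell (20290 genes), 38% and 66% for stromal-like (16067 genes), 46% and 92% for macrophage-like (13877 genes), 70% and 94% for osteoclast-like (12937 genes), 86% and 98% for T/NK-like (7955 genes), 72% and 92% for endothelial-like (11759 genes), 76% and 96% for CSF1 (3561 genes) and 84% and 94% for stromal-like against macrophage-like (15905 genes). 2-fold changes were recovered for 0% of genes in the all-cell and 34% in the CSF1 comparison. Unchanged genes made up 6% (all-cell), 9.8% (stromal-like), 10.5% (macrophage-like), 11.9% (osteoclast-like), 8.6% (T/NK-like), 6.3% (endothelial-like), 2% (CSF1) and 9.5% (stromal-like against macrophage-like) of the simulated calls, above the nominal 5% in each comparison except CSF1.

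Alternatives changed 1 choice at a time, but those that changed the kept cells also remade the clusters and their names, and osteoclast-like sums lost TGCT2, at under 20 cells, in 4 of them: 2000 UMIs, 10% mitochondrial UMIs, no doublet removal and the automatic doublet threshold. They were DESeq2 size factors and the DESeq2 1.42.0 Wald test, no filter on low counts, each tumour left out, other limits on UMIs and mitochondrial share, no doublet removal, the first library of each tumour, cells named by their highest marker score, clusters made within each tumour, Leiden resolution 2, subtraction of free RNA (profile of barcodes of 10 to 100 UMIs), the tumour number as a block, other CSF1 classes and thinning. Added after the data were seen were the automatic doublet threshold, the profile of barcodes of 100 to 500 UMIs, classes with or without doubtful clusters, thinning to 10000 UMIs, and ligand and receptor comparisons without the tumour block. With a GCTB tumour left out, the spread between tumours comes from TGCT alone. XIST, TSIX and Y-linked genes were left out of every test.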

Results

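RNA was measured cell by cell in 5 giant cell tumours. 3 were tenosynovial giant cell tumours (TGCT1 to TGCT3), which grow from the lining of joints and tendon sheaths. 2 were giant cell tumours of bone (GCTB1 and GCTB2), which grow inside bone. Both kinds hold multinucleated cells resembling osteoclasts, the cells that resorb bone. TGCT1, TGCT2 and GCTB2 gave 2 libraries each and TGCT3 and GCTB1 gave 1, so that 8 libraries stood for 5 independent tumours. The libraries held 115426451 and 111144214 unique molecular identifiers (UMIs, the counted RNA molecules) for TGCT1, 47449399 and 51908924 for TGCT2, 63590645 for TGCT3, 111540730 for GCTB1, and 61100887 and 54397320 for GCTB2. The filters kept 39954 cells, namely 10528 cells of TGCT1 at a median of 9882 UMIs, 5328 cells of TGCT2 at a median of 11394 UMIs, 2934 cells of TGCT3 at a median of 15132 UMIs, 8138 cells of GCTB1 at a median of 8222 UMIs and 13026 cells of GCTB2 at a median of 4858 UMIs. The study states 18788 cells after its own filtering, over a denominator that the sources used here do not define. Libraries of the same tumour correlated across genes at r = 0.9988 (TGCT1), 0.9978 (TGCT2) and 0.9963 (GCTB2), libraries of different tumours of the same type at 0.835 to 0.957, and libraries of different types at 0.739 to 0.842. Genes are not independent replicates, so these values carry no test. Among the named cell classes, libraries of the same tumour had shares differing by at most 16.3 percentage points in TGCT1, 2.99 in TGCT2 and 0.95 in GCTB2. The share of unnamed cells differed by more, most of all in TGCT1. With only the first library of each tumour, unnamed cells made up 10.5% ± 3.33 in TGCT (mean ± SD), in place of 15.9% ± 8.69.

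The composition of the tumours was compared as shares of kept cells, means ± SD over 3 TGCT and 2 GCTB tumours. Stromal-like cells, the collagen-producing class, made up 7.1% ± 1.87 in TGCT and 38% ± 19.3 in GCTB, and dendritic-like cells 0.353% ± 0.189 in TGCT and 4.85% ± 2.01 in GCTB. Neither overlapped between the tumour types, but at a minimum of 500 UMIs stromal-like cells did, at 7.32% in TGCT and 28.6% in GCTB (exact permutation p = 0.3), and there, at a minimum of 2000 UMIs, without doublet removal, at resolution 2 and with the automatic doublet threshold dendritic-like cells had no cluster. With clusters made in each tumour, for which shares were not tested, dendritic-like cells numbered 0, 0 and 70 in TGCT1, TGCT2 and TGCT3 and 236 and 0 in GCTB1 and GCTB2, which overlap. Their shares were 2.16% in TGCT and 6.16% in GCTB with a minimum per library and 0.993% in TGCT and 3.78% in GCTB by marker score, without overlap. Endothelial-like cells made up 18.9% ± 11.3 in TGCT and 1.95% ± 1.04 in GCTB, and mural-like cells, which wrap them, 11.3% ± 15.6 in TGCT and 0.613% ± 0.454 in GCTB, again without overlap. Macrophage-like cells made up 37.8% ± 19.9 in TGCT and 18.4% ± 1.57 in GCTB, osteoclast-like cells 5.18% ± 4.54 in TGCT and 6.07% ± 0.92 in GCTB and T/NK-like cells 3.51% ± 1.93 in TGCT and 6.35% ± 2.35 in GCTB, with overlapping values at the chosen settings. The exact permutation p was 0.1 for stromal-like and 0.1 for dendritic-like cells, 0.2 for endothelial-like, 0.3 for T/NK-like, 0.4 for macrophage-like, 0.5 for mural-like and 0.8 for osteoclast-like cells. 3 tumours against 2 cannot go below 0.1, and adjusted over the classes the lowest exact p was 0.4. Most stromal-like cells were in cluster 3 in TGCT and in clusters 24, 25, 28 and 29 in GCTB. Macrophage-like cells were mostly in clusters 0 and 7 in TGCT and in 16 and 18 in GCTB. Osteoclast-like cells were mostly in cluster 4 in TGCT and 12 in GCTB, whereas endothelial-like cells of GCTB shared cluster 2 with TGCT, whose others lay in cluster 6. Unnamed clusters held 15.9% ± 8.69 in TGCT and 23.8% ± 20.5 in GCTB. A limit on free RNA set after the data were seen kept out cluster 15 (6.62% of TGCT1 and 0.03% of TGCT3), which scored highest for osteoclast markers. With it, osteoclast-like cells were 1.33 percentage points higher in TGCT, as they were by 1.1 without TGCT2, in place of -0.887. Naming rules, whose details were settled after the data were seen, kept out clusters 27 and 30 (27.6% and 6.36% of GCTB2), which scored highest for stromal markers, cycling cluster 5, cluster 13 (14.5% of TGCT1) and 5 others. Free RNA could account for up to 96.9% of the UMIs of cluster 13 and 95.4% of those of cluster 15. Both stayed among the kept cells and in the sums of all cells. Without both, an alternative added after the data were seen, the macrophage-like difference was 23 percentage points in place of 19.4, and the stromal-like one -30.3. With clusters 27 and 30, an alternative added after the data were seen, stromal-like cells of GCTB were 55% ± 4.63 and the difference -47.9 percentage points in place of -30.9. Osteoclast-like shares were 0.798% in TGCT and 5.73% in GCTB at no more than 10% mitochondrial UMIs, 0.947% in TGCT and 4.21% in GCTB without doublet removal, and 0.956% in TGCT and 3.95% in GCTB with the automatic doublet threshold, added after the data were seen. These did not overlap (exact permutation p = 0.1 each), nor did those at a minimum of 2000 UMIs (2.15% in TGCT and 5.68% in GCTB, exact permutation p = 0.2) or without TGCT3 (2.71% in TGCT and 6.07% in GCTB). T/NK-like shares did not overlap at no more than 10% mitochondrial UMIs (3.02% in TGCT and 6.85% in GCTB, exact permutation p = 0.1), at a minimum of 500 UMIs (3.6% in TGCT and 6.99% in GCTB, exact permutation p = 0.2), without TGCT2 or without GCTB2. Macrophage-like shares did not with a minimum per library (48.6% in TGCT and 18.9% in GCTB), at resolution 2 (35.4% in TGCT and 14.2% in GCTB, exact permutation p = 0.2 for both) or without TGCT2. The T/NK-like difference of -2.84 points turned to 0.633 at a minimum of 2000 UMIs per cell.

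**Figure D1:**
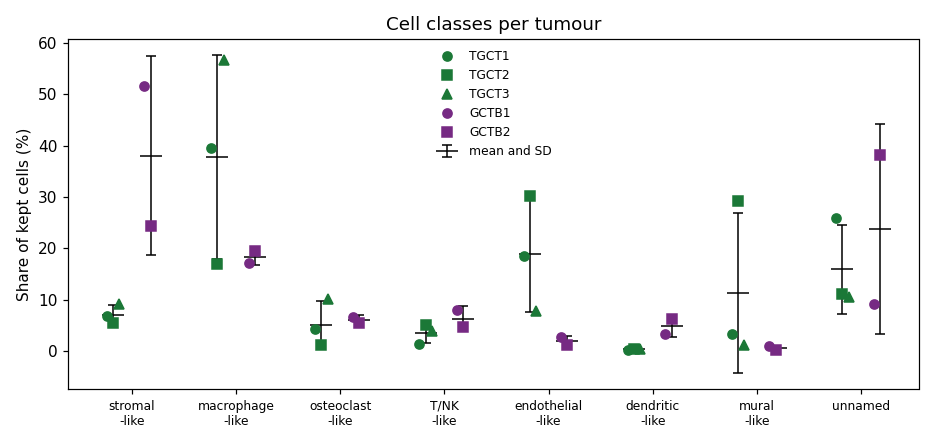
Share of kept cells in each cell class (percent, vertical axis) per tumour, with each point a tumour, and the mean and SD of 3 TGCT and 2 GCTB tumours beside them. Stromal-like and dendritic-like shares are higher in both GCTB tumours than in any TGCT tumour, and endothelial-like and mural-like shares are lower.

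Summed over all kept cells, the comparison asked how the tumour types differ in their whole RNA, cell composition included. Values are log2 fold changes of TGCT over GCTB ± SE from 3 and 2 tumours, here and for each class. The largest rises in TGCT by the rule for named genes were PLA2G2A, a secreted phospholipase (13.84 ± 1.71), THBS4 (7.71 ± 0.64), CRTAC1 (7.18 ± 1.07), TNXB (4.85 ± 0.78), COL14A1 (4.82 ± 0.77), ABI3BP (4.13 ± 0.49) and ITGA6 (3.51 ± 0.53) and the endothelial receptor partner RAMP3 (3.46 ± 0.53). The largest falls by the same rule were bone sialoprotein IBSP (-7.88 ± 0.82), the collagenase MMP13 (-6.75 ± 1.02) and MIA (-8.20 ± 1.05), MEGF10 (-7.09 ± 1.12), SLPI (-6.73 ± 0.41), FAM133A (-6.51 ± 0.48), COL10A1 (-6.12 ± 0.94) and FST (-5.53 ± 0.36). TNFSF11, which encodes the osteoclast-inducing ligand RANKL, was lower (-4.95 ± 0.71). CSF1, the macrophage growth factor that the series title names as the driver of TGCT, did not differ past the threshold (0.13 ± 0.52, edgeR adjusted p = 0.899). Neither did its receptor CSF1R (0.48 ± 0.56), the RANKL receptor TNFRSF11A (1.24 ± 0.75), its decoy TNFRSF11B (-0.28 ± 0.65) or the hexosamine enzyme GFPT2 (0.75 ± 0.59). Among 20 osteoblast lineage genes, 10 fell and 0 rose and 10 did not pass (0 higher and 14 lower adjusted over the list alone). By camera the osteoblast lineage list had adjusted p = 1.47e-23, and adjusted p = 0.0733 with an estimated correlation. SP7 (-6.25 ± 0.68) and MEPE (-5.79 ± 0.56) are examples. Among 16 synovial lining genes, 4 rose and 0 fell and 12 did not pass (10 higher and 0 lower adjusted over the list alone). The synovial lining list had camera adjusted p = 6.93e-10, and adjusted p = 0.278 with an estimated correlation. PRG4 (11.83 ± 1.66) and CLIC5 (4.63 ± 0.38) are examples. 392 of 20290 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 118 higher and 274 lower in TGCT. 44.8% of tested genes had no overlap between the tumour types, where chance gives a mean of 20% over the 10 splits of the tumours. Genes move together, so a single split can lie far from that mean. The other splits were not counted, here or for the classes, so these shares carry no test. Limma's camera put 11 of 22 gene lists past the threshold at the preset correlation, 3 up and 8 down in TGCT. 3 lists had an unadjusted p under 0.05 with an estimated correlation, where camera called 0 and the lowest adjusted p was 0.0733; fry called 1. The count rested on single tumours, being 0 without TGCT1, 0 without GCTB1 and 0 without GCTB2 by edgeR (3417, 2873 and 2653 genes at an unadjusted p under 0.05), so no gene named here passed there. It was 891 without TGCT3, and with all 5 tumours DESeq2's Wald test called 3472.

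Within stromal-like cells, the collagen-producing class, TGCT was set against GCTB, which removes the share of this class but not its make-up. Its cluster 3 held 681, 282 and 260 cells of TGCT1, TGCT2 and TGCT3 and 2 and 2 of GCTB1 and GCTB2. Clusters 24, 25, 28 and 29, where most GCTB cells of the class lay, held 0 TGCT cells. Expression within a cell type was thus not separated from which stromal-like cells a tumour held. PLA2G2A, at 2 UMIs in GCTB, was 141000 times higher in TGCT (counting interval 39020 to 1164000). The antimicrobial peptide gene DEFB1, at 1 UMI, was higher 11870 times (2129 to 468700), and TMEM196, at 3 UMIs, 1492 times (509.9 to 7240). The matrix genes TNXB (11.05 ± 0.85), CLEC3B (9.83 ± 0.85) and THBS4 (9.74 ± 0.46) rose, as did the collagenase gene MMP1 (11.78 ± 2.28) and the stromelysin gene MMP3 (10.16 ± 2.28). Their UMIs came mostly from different tumours. MMP1 had 13059 UMIs in TGCT3, 1329 in TGCT1 and 1019 in TGCT2, and MMP3 60, 6699 and 6259. The acute-phase gene SAA1, at 1 UMI in TGCT, was 3457 times higher in GCTB (counting interval 620.2 to 136600). IBSP (-6.35 ± 0.50), BMP8B (-6.48 ± 0.69), CDH15 (-6.57 ± 0.35) and CCN6 (-8.02 ± 0.72) fell, with ERMN (-7.14 ± 0.73) and MIA (-6.71 ± 1.12) and the heat-shock gene HSPA6 (-5.98 ± 0.51). GFPT2, the entry enzyme of hexosamine synthesis, rose (2.60 ± 0.42) and TNFSF11 fell (-2.77 ± 0.62). CSF1 was at 703 ± 625 CPM (UMIs scaled to a common total, mean ± SD) in TGCT and 213 ± 58 in GCTB, a difference that did not pass (1.84 ± 1.05, edgeR adjusted p = 0.323), nor did those of TNFRSF11A (2.15 ± 1.15), TNFRSF11B (2.20 ± 1.19) and CSF1R (0.89 ± 1.21). 1588 of 16067 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 857 higher and 731 lower in TGCT. 47.6% of tested genes had no overlap between the tumour types, where chance gives a mean of 20% over the splits. DESeq2's Wald test called 2871. The edgeR count was 962 without TGCT1 (35 of 41 passing genes named here), 639 without TGCT2 (29 of 41), 547 without GCTB1 (26 of 41) and 583 without GCTB2 (30 of 41).

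The fixed gene lists put names to the stromal-like difference. Among 16 synovial lining genes, 13 rose and 0 fell and 3 did not pass (13 higher and 0 lower adjusted over the list alone). By camera the synovial lining list had adjusted p = 4.34e-19, and adjusted p = 0.106 with an estimated correlation. PRG4 (13.30 ± 1.78) and MMP1 (11.78 ± 2.28) are examples. Among 18 sublining genes, 7 rose and 1 fell, with 10 not passing (12 higher and 1 lower adjusted over the list alone). The sublining list had camera adjusted p = 3.31e-08, and adjusted p = 0.135 with an estimated correlation. CXCL12 (5.87 ± 0.87), IGFBP5 (5.64 ± 0.72) and COMP (4.73 ± 0.88) are examples. Among 20 osteoblast lineage genes, 12 fell and 0 rose and 8 did not pass (1 higher and 14 lower adjusted over the list alone). By camera the osteoblast lineage list had adjusted p = 1.51e-12, and adjusted p = 0.135 with an estimated correlation. DLX5 (-5.75 ± 0.97), BMP2 (-5.66 ± 0.62) and MEPE (-5.05 ± 0.90) are examples. Among 17 complement genes, 7 rose and 0 fell and 10 did not pass (7 higher and 0 lower adjusted over the list alone). The complement list had camera adjusted p = 5.9e-06, and adjusted p = 0.135 with an estimated correlation. C3 (7.59 ± 0.89), CFD (5.86 ± 0.32) and C2 (2.96 ± 0.45) are examples. Hyaluronan, a matrix sugar polymer, is built from hexosamine products. Among 15 hexosamine and hyaluronan synthesis genes, 4 rose and 0 fell and 11 did not pass (8 higher and 0 lower adjusted over the list alone). By camera the hexosamine and hyaluronan synthesis list had adjusted p = 5.24e-05, and adjusted p = 0.162 with an estimated correlation. HAS1 (6.81 ± 0.81), UAP1 (3.11 ± 0.25) and UGP2 (2.66 ± 0.34) are examples. Among 24 matrix protease genes, 8 rose and 1 fell, with 15 not passing (10 higher and 4 lower adjusted over the list alone). The matrix protease list had camera adjusted p = 0.00993, and adjusted p = 0.162 with an estimated correlation. MMP13 (-4.81 ± 0.81) and ADAMTS12 (3.53 ± 0.64) are examples. Among 28 collagen and fibrillar matrix genes, 4 rose and 1 fell, with 23 not passing (8 higher and 2 lower adjusted over the list alone). By camera the collagen and fibrillar matrix list had adjusted p = 0.0012, and adjusted p = 0.414 with an estimated correlation. COL14A1 (6.63 ± 0.71) and ELN (6.27 ± 0.58) are examples. Among 20 cell cycle genes, 10 fell and 0 rose and 10 did not pass (0 higher and 15 lower adjusted over the list alone). The cell cycle list had camera adjusted p = 1.29e-09, and adjusted p = 0.414 with an estimated correlation. RRM2 (-5.35 ± 1.11) and UBE2C (-4.87 ± 1.03) are examples. Cycling cluster 22 of this class held 0, 1 and 0 cells of TGCT1, TGCT2 and TGCT3 and 73 and 252 of GCTB1 and GCTB2, while cycling cluster 5, left unnamed, held 190, 49 and 127 and 507 and 501. Whether cluster 5 holds stromal-like cells was not tested. With each cell named by marker score UBE2C was lower past the threshold and RRM2 was not. Among 16 TGF-beta response genes, 1 rose and 5 fell, with 10 not passing (2 higher and 9 lower adjusted over the list alone). By camera the TGF-beta response list had adjusted p = 0.00727, and adjusted p = 0.162 with an estimated correlation. ID1 (-4.03 ± 0.54) and CDKN1A (2.53 ± 0.26) are examples. Among 20 dissociation and immediate early genes, 6 fell and 0 rose and 14 did not pass (0 higher and 8 lower adjusted over the list alone). The dissociation and immediate early list had camera adjusted p = 8.86e-08, and adjusted p = 0.376 with an estimated correlation. HSPA1A (-3.70 ± 0.46) and HSPA1B (-3.55 ± 0.55) are examples. In this class limma's camera put 10 of 22 gene lists past the threshold at the preset correlation, 6 up and 4 down in TGCT. 5 lists had an unadjusted p under 0.05 with an estimated correlation, where camera called 0 and the lowest adjusted p was 0.106; fry called 9.

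**Figure D2:**
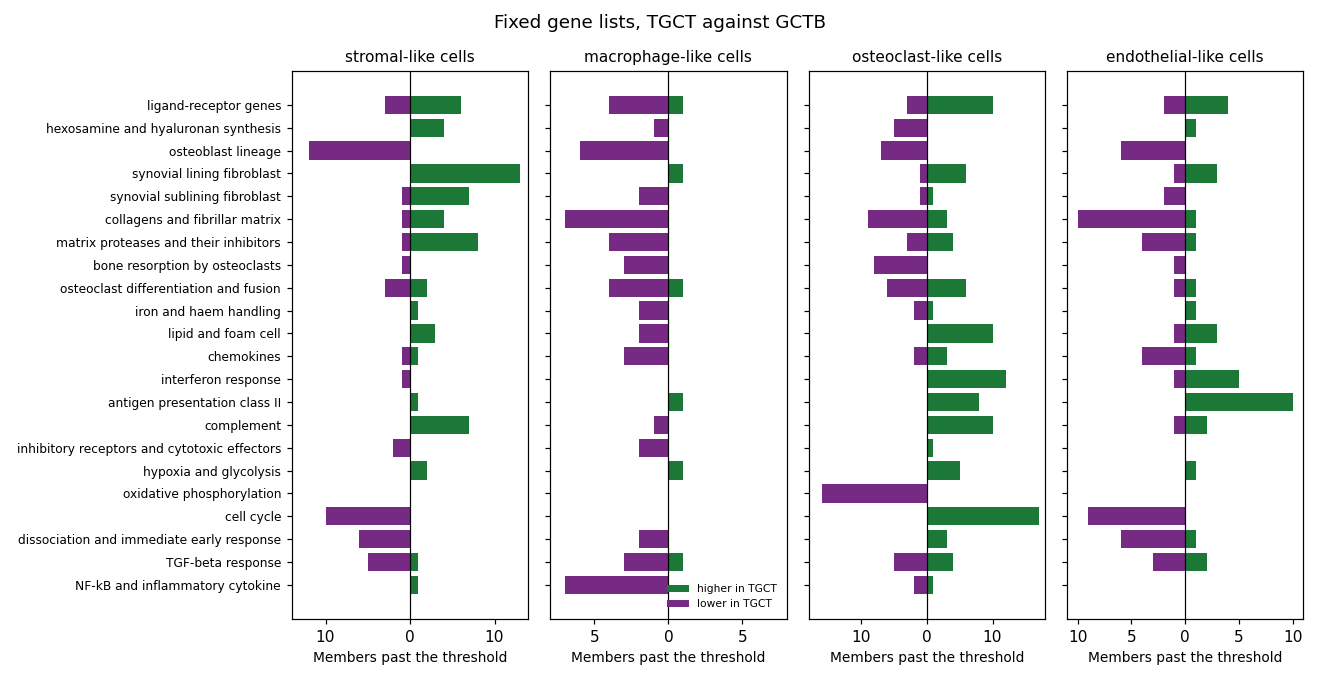
Number of members of each fixed gene list past the adjusted p threshold in edgeR, higher in TGCT to the right of 0 and lower to the left (horizontal axis, genes), for the stromal-like, macrophage-like, osteoclast-like and endothelial-like sums of 3 TGCT and 2 GCTB tumours. Lining genes are higher in the stromal-like sums and cell cycle genes are higher in the osteoclast-like sums of TGCT.

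Macrophage-like cells, the class that CSF1 recruits, were compared next. GABRB2 is a leading gene of cluster 0, IL2RA of cluster 16 and CXCL8 of cluster 18. Cluster 0 held 3543, 78 and 45 cells of TGCT1, TGCT2 and TGCT3 and 1 and 0 of GCTB1 and GCTB2. Cluster 16 held 6, 5 and 1 and 178 and 2237, and cluster 18 held 2, 1 and 3 and 786 and 31. Which macrophage-like cells a tumour held was not separated from a change in expression. In TGCT the adipogenesis factor ADIRF (5.24 ± 0.57), the ion channel genes GABRB2 (4.86 ± 0.64) and KCNQ3 (4.62 ± 0.34), and the cytoskeletal genes DPYSL3 (4.72 ± 0.76), TNS1 (2.29 ± 0.33) and ARHGAP24 (2.77 ± 0.30) rose, with CRIP1 (3.85 ± 0.70) and EMP1 (2.72 ± 0.44). ADIRF also rose in osteoclast-like (5.09) and endothelial-like sums (4.77). Its mean in TGCT was 929 CPM in endothelial-like and 162 in macrophage-like cells, and RNA from other cells was not separated for it. The interleukin 2 receptor chain IL2RA (-8.58 ± 0.83), the lipid enzymes PLA2G7 (-6.09 ± 0.59) and ENPP2 (-5.61 ± 0.35), the lipid receptor CD36 (-3.35 ± 0.55), the survival gene BCL2A1 (-4.01 ± 0.69) and the growth factor gene EREG (-3.40 ± 0.26) fell. BCL2A1 and EREG are leading genes of cluster 1, which scored 1.12 for neutrophil and 1.09 for macrophage markers and was named by its leading genes. Both passed with each cell named by marker score. MMP13 (-7.38 ± 0.70) and IBSP (-3.40 ± 0.64), genes of bone-forming cells, were also lower. Their ratio in GCTB macrophage-like cells lay within 1.455-fold of that in barcodes of 100 to 500 UMIs. With free RNA subtracted IBSP turned to 9.71, which did not pass (edgeR adjusted p = 0.117) and so shows no rise in TGCT. Among 12 osteoblast lineage genes, 6 fell and 0 rose and 6 did not pass (0 higher and 9 lower adjusted over the list alone). By camera the osteoblast lineage list had adjusted p = 1.67e-13, and adjusted p = 0.0863 with an estimated correlation. Among 26 collagen and fibrillar matrix genes, 7 fell and 0 rose and 19 did not pass (2 higher and 17 lower adjusted over the list alone). The collagen and fibrillar matrix list had camera adjusted p = 4.73e-12, and adjusted p = 0.191 with an estimated correlation. For both lists free RNA from stromal-like cells was not separated from a change in the class. Among 19 NF-kB and inflammatory cytokine genes, 7 fell and 0 rose and 12 did not pass (0 higher and 16 lower adjusted over the list alone). By camera the NF-kB and inflammatory cytokine list had adjusted p = 4.58e-17, and adjusted p = 0.168 with an estimated correlation. IL6 (-3.84 ± 0.47), TNFAIP6 (-3.33 ± 0.34) and TRAF1 (-3.22 ± 0.42) are examples. Among 20 chemokine genes, 3 fell and 0 rose and 17 did not pass (0 higher and 12 lower adjusted over the list alone). The chemokine list had camera adjusted p = 4.28e-09, and adjusted p = 0.112 with an estimated correlation. CCL4 (-3.04 ± 0.46), CCL3 (-2.52 ± 0.32) and CXCL8 (-2.40 ± 0.43) are examples. Among 20 bone resorption genes, 3 fell and 0 rose and 17 did not pass (0 higher and 4 lower adjusted over the list alone). By camera the bone resorption list had adjusted p = 1.18e-06, and adjusted p = 0.112 with an estimated correlation. CA2 (-4.62 ± 0.33), ATP6V0D2 (-4.25 ± 0.41) and MMP9 (-3.59 ± 0.55) are examples. CA2 and MMP9 are leading genes of osteoclast-like cluster 12, with 19, 4 and 4 cells of TGCT1, TGCT2 and TGCT3 and 544 and 698 of GCTB1 and GCTB2. For this list RNA from osteoclast-like cells was not separated from a change in the class. Among 17 iron and haem genes, 2 fell and 0 rose and 15 did not pass (0 higher and 9 lower adjusted over the list alone). The iron and haem list had camera adjusted p = 5.71e-07, and adjusted p = 0.112 with an estimated correlation. SLC40A1 (-2.94 ± 0.25) and SLC48A1 (-2.06 ± 0.20) are examples. Among 10 inhibitory receptor and cytotoxic genes, 2 fell and 0 rose and 8 did not pass (0 higher and 4 lower adjusted over the list alone). By camera the inhibitory receptor and cytotoxic list had adjusted p = 0.0247, and adjusted p = 0.19 with an estimated correlation. That list's median was 0.15 and its mean -0.95, with the test downward. Among 14 synovial lining genes, 1 rose and 0 fell and 13 did not pass (6 higher and 2 lower adjusted over the list alone). The synovial lining list had camera adjusted p = 0.00429, and adjusted p = 0.168 with an estimated correlation. Among 25 interferon response genes, none passed the threshold in either direction (6 higher and 2 lower adjusted over the list alone). By camera the interferon response list had adjusted p = 0.0177, and adjusted p = 0.289 with an estimated correlation. Among 15 class II antigen presentation genes, 1 rose and 0 fell and 14 did not pass (1 higher and 0 lower adjusted over the list alone). The class II antigen presentation list had camera adjusted p = 0.00429, and adjusted p = 0.327 with an estimated correlation. These 3 lists were the ones past the threshold upward, and for the lining list free RNA was not separated either. CSF1R (0.07 ± 0.36), TNFRSF11A (1.78 ± 0.40), CSF1 (-2.75 ± 0.63), TNFSF11 (-3.00 ± 1.05), GFPT2 (-1.67 ± 0.94) and TNFRSF11B (0.29 ± 1.57) did not pass. 414 of 13877 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 115 higher and 299 lower in TGCT. 43.1% of tested genes had no overlap between the tumour types, where chance gives a mean of 20% over the splits. Limma's camera put 19 of 22 gene lists past the threshold at the preset correlation, 3 up and 16 down in TGCT. 6 lists had an unadjusted p under 0.05 with an estimated correlation, where camera called 0 and the lowest adjusted p was 0.0863; fry called 9. The edgeR count was 185 without TGCT1 (25 of 29 passing genes named here), 88 without TGCT2 (19 of 29), 81 without TGCT3 (14 of 29), 48 without GCTB1 (9 of 29) and 95 without GCTB2 (14 of 29), 136 with free RNA subtracted, 244 with clusters made in each tumour, 816 at a minimum of 2000 UMIs, and 1461 by DESeq2's Wald test.

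Osteoclast-like cells, the class named by osteoclast markers, were compared between the tumour types. The scavenger receptor genes MSR1 (4.68 ± 0.51) and COLEC12 (4.28 ± 0.65), the matrix gene FN1 (4.74 ± 0.53), the chemokine gene CXCL2 (4.16 ± 1.08), the leukotriene enzyme LTC4S (5.15 ± 0.64), the fructose transporter SLC2A5 (4.11 ± 0.40), the channel KCNMA1 (5.50 ± 0.76) and ADIRF (5.09 ± 0.77) rose in TGCT. As in macrophage-like cells, RNA from other cells was not separated for ADIRF. The protease inhibitor SPINK2 (-8.12 ± 0.37), MMP13 (-7.43 ± 0.86), TSPAN13 (-5.78 ± 0.43), TM4SF1 (-5.37 ± 0.46), CCDC189 (-4.99 ± 0.28), CLDN14 (-4.87 ± 0.59) and SULT1B1 (-4.84 ± 0.60) and the kinase MAST4 (-4.48 ± 0.46) fell. For MMP13, free RNA from stromal-like cells was not separated from a change in the class. The ratio of IBSP to MMP13 UMIs in osteoclast-like cells lay 1.818-fold from that in free RNA in GCTB1 and 1.056-fold in GCTB2. GFPT2 fell too (-3.63 ± 0.92, 7, 0 and 0 UMIs in TGCT1, TGCT2 and TGCT3 and 52 and 18 in GCTB1 and GCTB2), but turned to 1.08 with cells named by marker score and to 0.85 with the unnamed osteoclast-scoring cluster, added after the data were seen. CSF1 (-2.01 ± 0.69), TNFRSF11A (0.67 ± 0.22), CSF1R (0.37 ± 0.23) and TNFRSF11B (-0.79 ± 0.92) did not pass. Among 20 cell cycle genes, 17 rose and 0 fell and 3 did not pass (18 higher and 0 lower adjusted over the list alone). By camera the cell cycle list had adjusted p = 1.08e-13, and adjusted p = 0.34 with an estimated correlation. TOP2A (4.42 ± 0.39) and UBE2C (3.84 ± 0.78) are examples. With each cell named by its highest marker score the list's median turned from 2.29 to -0.06, and in TGCT the cells with 2 or more cell cycle UMIs held 0.232 to 0.566 of the osteoclast marker level of the others. Its markers as a whole stood at other levels too. In its cells with fewer than 2 cell cycle UMIs, macrophage markers stood at 6027, 6841 and 8086 CPM in TGCT1, TGCT2 and TGCT3 and 3164 and 3583 in GCTB1 and GCTB2, and osteoclast markers at 19894, 8636 and 7910 and 36223 and 37294. The differences of the named genes and of the lists below, resorption, complement, class II and lipid among them, were not separated from these shifts. The shifts have no test. KCNMA1 is also a leading gene of macrophage-like cluster 0. Cluster 4 held 426, 60 and 293 cells of TGCT1, TGCT2 and TGCT3 and 3 and 8 of GCTB1 and GCTB2. Cluster 12 held 19, 4 and 4 and 544 and 698. Which osteoclast-like cells a tumour held was not separated from a change in expression. Among 11 osteoblast lineage genes, 7 fell and 0 rose and 4 did not pass (0 higher and 8 lower adjusted over the list alone). The osteoblast lineage list had camera adjusted p = 1.22e-06, and adjusted p = 0.173 with an estimated correlation. Among 24 collagen and fibrillar matrix genes, 3 rose and 9 fell, with 12 not passing (3 higher and 13 lower adjusted over the list alone). By camera the collagen and fibrillar matrix list had adjusted p = 3.46e-05, and adjusted p = 0.34 with an estimated correlation. Free RNA from stromal-like cells was not separated from these either. Among 20 bone resorption genes, 8 fell and 0 rose and 12 did not pass (1 higher and 13 lower adjusted over the list alone). The bone resorption list had camera adjusted p = 1.08e-08, and adjusted p = 0.366 with an estimated correlation. CA2 (-5.33 ± 0.40) and ATP6V0D2 (-2.84 ± 0.52) are examples. Among 23 nuclear oxidative phosphorylation genes, 16 fell and 0 rose and 7 did not pass (0 higher and 23 lower adjusted over the list alone). By camera the nuclear oxidative phosphorylation list had adjusted p = 3.35e-10, and adjusted p = 0.207 with an estimated correlation. COX5A (-1.42 ± 0.26) and CYC1 (-1.38 ± 0.25) are examples. Among 25 interferon response genes, 12 rose and 0 fell and 13 did not pass (20 higher and 1 lower adjusted over the list alone). The interferon response list had camera adjusted p = 3.17e-09, and adjusted p = 0.207 with an estimated correlation. IFI44L (4.17 ± 0.69) and IFI27 (3.48 ± 0.38) are examples. Among 15 class II antigen presentation genes, 8 rose and 0 fell and 7 did not pass (13 higher and 0 lower adjusted over the list alone). By camera the class II antigen presentation list had adjusted p = 4.04e-06, and adjusted p = 0.358 with an estimated correlation. CIITA (3.58 ± 0.72) and CD74 (2.48 ± 0.60) are examples. Among 18 complement genes, 10 rose and 0 fell and 8 did not pass (11 higher and 4 lower adjusted over the list alone). The complement list had camera adjusted p = 1.97e-04, and adjusted p = 0.173 with an estimated correlation. VSIG4 (3.78 ± 0.58) and C1QC (3.41 ± 0.61) are examples. Among 21 lipid and foam cell genes, 10 rose and 0 fell and 11 did not pass (11 higher and 1 lower adjusted over the list alone). By camera the lipid and foam cell list had adjusted p = 2.42e-04, and adjusted p = 0.358 with an estimated correlation. TREM2 (4.64 ± 1.20) and ABCG1 (4.13 ± 0.71) are examples. Among 22 osteoclast differentiation and fusion genes, 6 rose and 6 fell, with 10 not passing (7 higher and 11 lower adjusted over the list alone). The osteoclast differentiation and fusion list had camera adjusted p = 0.476, and adjusted p = 0.62 with an estimated correlation. OCSTAMP (-4.35 ± 0.83) and IRF8 (4.26 ± 0.88) are examples. Among 38 ligand-receptor genes, 10 rose and 3 fell, with 25 not passing (17 higher and 4 lower adjusted over the list alone). By camera the ligand-receptor list had adjusted p = 0.0288, and adjusted p = 0.366 with an estimated correlation. TNF (3.69 ± 0.86) and CD274 (-2.92 ± 0.55) are examples. 2414 of 12937 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 1271 higher and 1143 lower in TGCT. 53.3% of tested genes had no overlap between the tumour types, where chance gives a mean of 20% over the splits. Limma's camera put 12 of 22 gene lists past the threshold at the preset correlation, 7 up and 5 down in TGCT. 5 lists had an unadjusted p under 0.05 with an estimated correlation, where camera called 0 and the lowest adjusted p was 0.173; fry called 5. This class depended on the settings, and in 4 of them TGCT2 had too few osteoclast-like cells for a sum: 9 without doublet removal, 9 with the automatic doublet threshold, 9 at no more than 10% mitochondrial UMIs and 19 at a minimum of 2000 UMIs. These 4 settings also remade the clusters, so their values do not separate the setting from either change. Without doublet removal the edgeR count was 1076 and FN1 (-0.05), COLEC12 (-1.12), CXCL2 (-1.13), C1QC (-0.15), CIITA (-0.05), CD74 (-0.31) and IRF8 (-1.22) turned. With the automatic doublet threshold it was 870 and COLEC12 (-0.17), CXCL2 (-0.71), CIITA (-0.21) and CD74 (-0.35) turned. None of these genes turned when TGCT2 alone was left out. UBE2C turned to -0.30 with cells named by marker score. With clusters made in each tumour it was 0 (1924 at an unadjusted p under 0.05, with DESeq2 at 2831 on the main sums), and by marker score 578. It was 3738 without TGCT1 (35 of 35 passing genes named here), 1293 without TGCT2 (31 of 35), 1238 without TGCT3 (28 of 35), 91 without GCTB1 (9 of 35) and 544 without GCTB2 (19 of 35), and 411 at no more than 10% mitochondrial UMIs.

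T/NK-like cells, the lymphocyte class, were compared in the same way. The interferon-induced gene IFI44L (2.11 ± 0.35), the T cell genes THEMIS (1.31 ± 0.26) and CD226 (1.28 ± 0.26), the transcription factor MYBL1 (1.36 ± 0.31) and ANKRD28 (1.99 ± 0.35), C1orf56 (1.83 ± 0.29), PCSK7 (1.52 ± 0.25) and ATP2B1 (1.15 ± 0.26) rose in TGCT. The inhibitory receptor LAYN (-3.01 ± 0.48), the haem enzyme HMOX1 (-3.88 ± 0.47), the adhesion gene VCAM1 (-3.80 ± 0.38), osteopontin SPP1 (-2.90 ± 0.55) and the chemokine CXCL8 (-2.80 ± 0.42) fell. Without doublet removal HMOX1 turned to 0.73. SPP1 stood at 12730 and 1786 CPM in stromal-like cells of GCTB1 and GCTB2, against a mean of 566 in T/NK-like cells of GCTB. HMOX1 and CXCL8 are leading genes of macrophage-like cluster 18, most of whose cells were from GCTB. For SPP1, HMOX1 and CXCL8, RNA from other cells was not separated from a change in the class. MMP13 and IBSP, at 1 UMI each in TGCT, were 420.1 and 191.9 times higher in GCTB (counting intervals 75.09 to 16620 and 34.14 to 7609), and PPP1R2C, at 3 UMIs, 54.4 times (18.37 to 265.9). The MMP13 and IBSP UMIs of GCTB again stood in nearly the ratio of the barcodes of 100 to 500 UMIs, within 1.455-fold. CSF1 (0.29 ± 0.35) and CSF1R (-0.96 ± 0.64) did not pass, and too few UMIs of TNFSF11, TNFRSF11A, TNFRSF11B and GFPT2 were present for a test. Among 6 osteoblast lineage genes, 5 fell and 0 rose and 1 did not pass (0 higher and 5 lower adjusted over the list alone). The osteoblast lineage list had camera adjusted p = 1e-20, and adjusted p = 0.0537 with an estimated correlation. Among 15 collagen and fibrillar matrix genes, 7 fell and 0 rose and 8 did not pass (0 higher and 12 lower adjusted over the list alone). By camera the collagen and fibrillar matrix list had adjusted p = 3.19e-29, and adjusted p = 0.147 with an estimated correlation. DCN (-3.91 ± 0.38) and COL1A1 (-3.34 ± 0.39) are examples. These are stromal transcripts, as IBSP and MMP13 are, and for both lists free RNA from stromal-like cells was not separated from a change in the class. COL1A1 passed with free RNA subtracted but not with cells named by marker score or with clusters per tumour. With free RNA subtracted DCN kept too few UMIs for a test. Among 20 dissociation and immediate early genes, 2 fell and 0 rose and 18 did not pass (0 higher and 9 lower adjusted over the list alone). The dissociation and immediate early list had camera adjusted p = 5.92e-09, and adjusted p = 0.282 with an estimated correlation. HSPA1B (-2.62 ± 0.50) and HSP90AA1 (-2.53 ± 0.44) are examples. Among 18 inhibitory receptor and cytotoxic genes, 1 fell and 0 rose and 17 did not pass (4 higher and 4 lower adjusted over the list alone). By camera the inhibitory receptor and cytotoxic list had adjusted p = 0.975, and adjusted p = 0.982 with an estimated correlation. Its median was 0.15 and its mean -0.10. 131 of 7955 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 23 higher and 108 lower in TGCT. 29.9% of tested genes had no overlap between the tumour types, where chance gives a mean of 20% over the splits. Limma's camera put 13 of 21 gene lists past the threshold at the preset correlation, 1 up and 12 down in TGCT. 6 lists had an unadjusted p under 0.05 with an estimated correlation, where camera called 0 and the lowest adjusted p was 0.0537; fry called 2. The edgeR count was 56 without TGCT2 (17 of 20 passing genes named here), 25 without TGCT3 (10 of 20) and 65 without GCTB1 (14 of 20), 21 with each cell named by marker score, 8 with clusters made in each tumour, 86 with free RNA subtracted, 255 without doublet removal and 224 at a minimum of 2000 UMIs.

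Endothelial-like cells, which line vessels, were compared last. The homeobox gene MEOX1, at 3 UMIs in GCTB, was 85.73 times higher in TGCT (counting interval 29.32 to 415.8), ITIH5, at 2 UMIs, 70.88 times (19.6 to 585.6) and ANKRD29, at 3 UMIs, 67.34 times (23.02 to 326.7). The leukocyte-capturing adhesion gene SELP (5.95 ± 0.55), EPB41L3 (6.02 ± 0.86), ADIRF (4.77 ± 0.28), LRATD2 (4.59 ± 0.45) and PDLIM3 (4.32 ± 0.34) rose. SELP is a leading gene of cluster 6, which held 1027, 1183 and 148 cells of TGCT1, TGCT2 and TGCT3 and 5 and 6 of GCTB1 and GCTB2. Cluster 2, the other of this class, held 927, 430 and 80 and 213 and 152. Which endothelial-like cells a tumour held was not separated from a change in expression. The matrix protease gene ADAMTS5 (-6.43 ± 0.33), the membrane peptidase FOLH1 (-5.89 ± 0.76), ARHGAP6 (-5.25 ± 0.36), MAF (-4.88 ± 0.44) and MFAP2 (-4.71 ± 0.60) and the mechanosensitive channel PIEZO2 (-4.33 ± 0.32) fell, with MMP13 (-8.07 ± 0.86) and IBSP (-7.32 ± 0.38), whose ratio in GCTB was within 1.455-fold of that in barcodes of 100 to 500 UMIs. Among 15 class II antigen presentation genes, 10 rose and 0 fell and 5 did not pass (12 higher and 0 lower adjusted over the list alone). The class II antigen presentation list had camera adjusted p = 8.05e-12, and adjusted p = 0.299 with an estimated correlation. CD74 (4.16 ± 0.78) and HLA-DMA (3.99 ± 0.60) are examples. CD74 is also a leading gene of macrophage-like cluster 7. That cluster held 244, 743 and 1558 cells of TGCT1, TGCT2 and TGCT3 and 18 and 13 of GCTB1 and GCTB2. For this list RNA from macrophage-like cells was not separated from a change in the class. Among 25 interferon response genes, 5 rose and 1 fell, with 19 not passing (9 higher and 1 lower adjusted over the list alone). By camera the interferon response list had adjusted p = 4.53e-07, and adjusted p = 0.463 with an estimated correlation. IFIT1 (3.66 ± 0.83) and MX1 (3.50 ± 0.58) are examples. Among 25 collagen and fibrillar matrix genes, 1 rose and 10 fell, with 14 not passing (1 higher and 15 lower adjusted over the list alone). The collagen and fibrillar matrix list had camera adjusted p = 7.69e-11, and adjusted p = 0.221 with an estimated correlation. POSTN (5.78 ± 0.60) and DCN (-4.24 ± 0.58) are examples. Among 12 osteoblast lineage genes, 6 fell and 0 rose and 6 did not pass (1 higher and 9 lower adjusted over the list alone). By camera the osteoblast lineage list had adjusted p = 8.05e-12, and adjusted p = 0.101 with an estimated correlation. As in T/NK-like cells, free RNA from stromal-like cells was not separated from a change in the class for these lists, and with it subtracted DCN kept too few UMIs for a test. Among 19 cell cycle genes, 9 fell and 0 rose and 10 did not pass (0 higher and 12 lower adjusted over the list alone). The cell cycle list had camera adjusted p = 1.29e-10, and adjusted p = 0.42 with an estimated correlation. UBE2C (-4.13 ± 0.84) and MKI67 (-3.42 ± 0.55) are examples. Among 20 hypoxia and glycolysis genes, 1 rose and 0 fell and 19 did not pass (1 higher and 0 lower adjusted over the list alone). By camera the hypoxia and glycolysis list had adjusted p = 0.0833, and adjusted p = 0.608 with an estimated correlation. PFKP (2.12 ± 0.28) is an example. CSF1 (1.02 ± 0.25, edgeR adjusted p = 0.051), TNFRSF11B (-1.57 ± 0.49) and CSF1R (0.77 ± 1.39) did not pass. TNFRSF11A, at 3 UMIs in GCTB, was 3.593 times higher in TGCT (counting interval 1.213 to 17.56) and did not pass either. 886 of 11759 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 413 higher and 473 lower in TGCT. 47.2% of tested genes had no overlap between the tumour types, where chance gives a mean of 20% over the splits. Limma's camera put 10 of 21 gene lists past the threshold at the preset correlation, 3 up and 7 down in TGCT. 2 lists had an unadjusted p under 0.05 with an estimated correlation, where camera called 0 and the lowest adjusted p was 0.101; fry called 2. The edgeR count was 15 without GCTB1 (6 of 25 passing genes named here) and 123 without GCTB2 (14 of 25), leaving a single GCTB tumour of 158 or 218 endothelial-like cells, and 2111 with no filter on low counts.

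The series title concerns CSF1-driven tumours, so 47 ligand and receptor genes, kept out of the clustering, were compared between classes of the same TGCT tumours. Values are log2 fold changes ± SE from 3 tumours, with the tumour as a block. CSF1 was 7.88 ± 0.69 higher in stromal-like than in macrophage-like cells, and IL34, the other CSF1R ligand, 7.41 ± 0.29. CSF1R was the reverse at -5.96 ± 0.99. CSF1 was not limited to stromal-like cells. In TGCT2 mural-like cells held 2271 CSF1 UMIs at 120 CPM and stromal-like cells 485 at 74.7. TNFSF11 was 5.93 ± 0.65 higher in stromal-like cells and its receptor gene TNFRSF11A differed by -5.06 ± 0.64. The cytokine receptor OSMR (7.95 ± 0.21), the growth factor FGF7 (8.10 ± 0.42), the guidance gene SEMA3A (5.96 ± 0.51) and the platelet-derived growth factor receptors PDGFRA (7.32 ± 0.35) and PDGFRB (7.27 ± 0.28) were higher in stromal-like cells, while PDGFB (-6.54 ± 0.56) and CSF2RA (-5.26 ± 0.41) were lower. Between osteoclast-like and macrophage-like cells, TNFRSF11A was 1.05 ± 0.20 higher in the former. CSF1R (0.31 ± 0.16) and CSF1 (0.10 ± 0.41) did not pass. The growth factor genes IGF1 (-4.68 ± 0.21), HGF (-3.24 ± 0.25), PDGFC (-2.29 ± 0.15), PDGFB (-1.44 ± 0.15) and TGFB2 (-2.00 ± 0.18) and the chemokine gene CXCL12 (-3.73 ± 0.39) were lower, as were the receptors NRP1 (-1.46 ± 0.12) and CSF2RA (-1.56 ± 0.14). Adjusted over the list alone, 34 of 44 tested genes differed between stromal-like and macrophage-like cells (16 higher and 18 lower, 33 over all genes), and 30 of 39 between osteoclast-like and macrophage-like cells (7 and 23, 28 over all genes). In GCTB 33 of 45 differed between stromal-like and macrophage-like cells. The difference of this class difference between tumour types was tested as an interaction, and passed for 20 of 45 genes adjusted over the list alone (14 higher and 6 lower in TGCT, 11 over all genes). CSF1 differed by 3.93 ± 0.86 (edgeR adjusted p = 0.0117 over the list and 0.0468 over all genes), whereas CSF1R (0.06 ± 1.16), IL34 (2.36 ± 0.98), TNFSF11 (0.48 ± 0.82) and TNFRSF11A (-0.11 ± 0.87) did not pass. Stromal-like CSF1 stood at 709, 74.7 and 1325 CPM in TGCT1, TGCT2 and TGCT3 and 254 and 172 in GCTB1 and GCTB2, so TGCT2 lay below both. Macrophage-like CSF1 stood at 3, 1.08 and 2 and 20.9 and 5.17 CPM, lower in TGCT, and in each tumour below the level in its barcodes of 100 to 500 UMIs. The interaction is therefore not a test of higher stromal-like CSF1 in TGCT. A macrophage-like level below that of the barcodes does not show where its CSF1 UMIs come from. By the profile of these barcodes, the upper bound of free RNA in macrophage-like cells ran from 3.14% to 16.3% per library. Without GCTB1 the CSF1 interaction was 3.15 with edgeR adjusted p = 0.0619 over the list, and over all alternatives its adjusted p ran from 0.00465 to 0.0935.

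**Figure D3:**
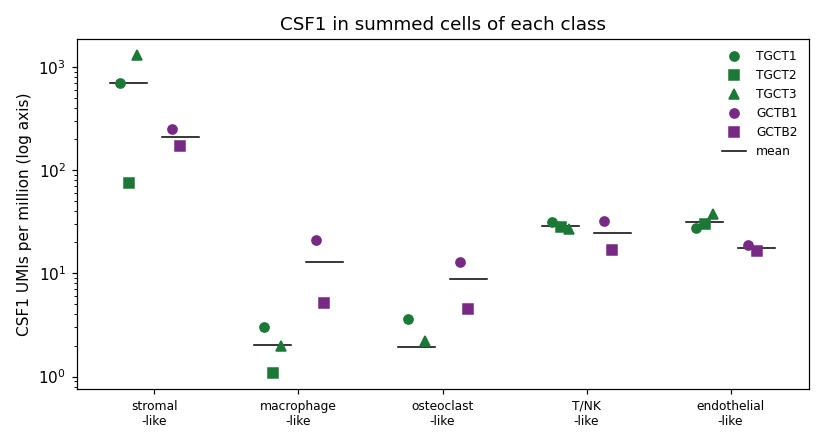
CSF1 level (CPM, logarithmic vertical axis) in the summed UMIs of each cell class, with each point a tumour; osteoclast-like cells of TGCT2 hold 0 CSF1 UMIs and are not drawn, nor are mural-like cells. Stromal-like cells lie between 74.7 and 1325 CPM, and macrophage-like cells between 1.08 and 20.9.

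To ask which genes go with CSF1, stromal-like TGCT cells with 2 or more CSF1 UMIs were set against those with 0 in the same tumours, each cell thinned to 2000 UMIs (628, 106 and 173 cells with and 32, 109 and 64 without in TGCT1, TGCT2 and TGCT3). The Wnt antagonist gene SFRP2 was lower in the cells with CSF1 (-2.78 ± 0.30, edgeR adjusted p = 0.00908), in all 3 tumours, and was the 1 gene of 3561 past the threshold. 450 had an unadjusted p under 0.05. No other gene passed. Of the genes with the smallest unadjusted p, those higher with CSF1 were CHI3L1 (2.51 ± 0.40), MMP3 (2.47 ± 0.46), GJB2 (2.13 ± 0.31), CD55 (1.96 ± 0.33), NTN4 (1.92 ± 0.33), SOX5 (1.76 ± 0.34), ACKR3 (1.59 ± 0.30), STEAP4 (1.44 ± 0.25), VKORC1 (1.38 ± 0.26) and SAT1 (1.16 ± 0.20). Those lower were DIO2 (-2.57 ± 0.50), CXCL14 (-2.17 ± 0.40), PTN (-1.44 ± 0.27), TSC22D1 (-1.37 ± 0.27) and FBLN2 (-1.27 ± 0.23), with edgeR adjusted p of 0.0614 to 0.0621. Stromal-like cells with a CSF1 UMI made up 93.1% of the class in TGCT1, 60.1% in TGCT2 and 73.8% in TGCT3 at median depths of 27689, 19511 and 24609 UMIs. The shares were 3.43%, 0.772% and 2.88% of macrophage-like cells at 11657, 13825 and 14872 UMIs. At an equal depth of 2000 UMIs they were 66.5%, 13.5% and 55.6% of stromal-like and 0.707%, 0.34% and 0.303% of macrophage-like cells in TGCT1, TGCT2 and TGCT3. The count depended on the setting, at 153 genes without thinning, 33 by DESeq2's Wald test, 90 without TGCT1, 11 without TGCT2 and 2 without TGCT3.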

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

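Every test in this part of differences between tumour types was planned; the level of CSF1 in barcodes of 100 to 500 UMIs was looked at only after the data were seen. The difference between stromal-like and macrophage-like cells was itself different between TGCT and GCTB, by the edgeR interaction test adjusted over the list, for 9 of the genes named from the ligand and receptor list. It was higher in TGCT by 6.03 ± 0.83 (log2 ± SE) for the growth factor IGF1, 3.93 ± 0.86 for CSF1, 3.22 ± 0.63 for SEMA3A, 2.75 ± 0.45 for the interleukin 6 receptor IL6R, 2.68 ± 0.46 for PDGFRA, 2.49 ± 0.38 for OSMR and 1.82 ± 0.33 for SIRPA, and lower by -2.10 ± 0.35 for the TGF-beta receptor TGFBR1 and -1.97 ± 0.35 for its ligand TGFB2. These genes were singled out because the test of the difference passed. A higher difference need not mean a higher stromal-like level in TGCT. Stromal-like SEMA3A stood at 17.55, 38.99 and 11.3 CPM in TGCT1, TGCT2 and TGCT3 and 30.86 and 58.78 in GCTB1 and GCTB2. In macrophage-like cells it stood at 0.154, 0.308 and 0.453 and 4.318 and 6.125. OSMR and PDGFRA were higher in stromal-like cells of TGCT, but their macrophage-like levels were also low, at 0.231 to 3.51 CPM. No explanation of these differences was tested; tumour type stays open as an untested biological one, and with the profile of barcodes of 10 to 100 UMIs subtracted the CSF1 difference was 7.27.

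CSF1 was also counted in barcodes of 100 to 500 UMIs, which hold too few UMIs to be kept as cells. Its level there was 51.8 CPM in TGCT1, 17.7 in TGCT2, 119 in TGCT3, 91.1 in GCTB1 and 63.8 in GCTB2, from 46 to 2875 UMIs of CSF1 per tumour, which is above the limit that a count of 0 allows. CSF1 in macrophage-like cells was below these levels in every tumour, from 1.08 CPM in TGCT2 to 20.9 in GCTB1, which leaves its source open. In stromal-like cells it was 74.7 CPM in TGCT2, below 254 in GCTB1 and 172 in GCTB2, so the CSF1 interaction does not show a higher level in the stromal-like cells of TGCT. No explanation was tested for these levels.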

How the results depend on the processing

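Alternatives marked as added, and ligand and receptor comparisons without the tumour block, were chosen only after the result was seen; the rest were planned. Counts of genes past the threshold were 392 for all cells, 1588 for stromal-like, 414 for macrophage-like, 2414 for osteoclast-like, 131 for T/NK-like, 886 for endothelial-like and 1 for CSF1, and moved by over 1.5 times as follows. With no filter on low counts they were 794 for all cells, 461 for T/NK-like, 2111 for endothelial-like and 144 for CSF1. At 10% mitochondrial UMIs they were 198 for all cells, 411 for osteoclast-like and 12 for CSF1. By DESeq2's Wald test they were 3472 for all cells, 2871 for stromal-like, 1461 for macrophage-like, 1333 for endothelial-like and 33 for CSF1. At 2000 UMIs per cell they were 816 for macrophage-like, 1296 for osteoclast-like, 224 for T/NK-like and 30 for CSF1. With clusters made in each tumour they were 244 for macrophage-like, 0 for osteoclast-like and 8 for T/NK-like. With the free RNA of barcodes of 10 to 100 UMIs subtracted they were 136 for macrophage-like and 86 for T/NK-like. With that of barcodes of 100 to 500 UMIs subtracted (added) they were 119 for macrophage-like and 76 for T/NK-like. With the automatic doublet threshold (added) they were 778 for macrophage-like and 870 for osteoclast-like. Without doublet removal they were 1076 for osteoclast-like, 255 for T/NK-like and 20 for CSF1. With cells named by marker score they were 578 for osteoclast-like and 21 for T/NK-like. With 1 or more CSF1 UMIs they were 19 for CSF1. Without thinning they were 153 for CSF1. Thinned to 10000 UMIs (added) they were 112 for CSF1. Where the osteoclast-like count was 0 in edgeR, 1924 genes had an unadjusted p under 0.05. At 2000 UMIs, 10% mitochondrial UMIs, without doublet removal and with the automatic doublet threshold the osteoclast-like sums also lacked TGCT2 (19, 9, 9 and 9 cells). The CSF1 sums kept TGCT1, with 18 cells without CSF1 at 10% mitochondrial UMIs and 15 at 10000 UMIs. The cause of these changes was not tested.

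No pairing by tumour number was seen: deviations from the group means correlated at -0.038 and -0.035 for tumours with the same number. The deviations of 2 GCTB tumours from their mean are opposite, so this check is weak and does not exclude pairing. With the number as a replicate block the counts were 73 for macrophage-like and 1525 for osteoclast-like cells, and moved by less than 1.5 times in the other classes. Without the tumour block, the CSF1 count was 0 in edgeR (289 at an unadjusted p under 0.05, and 33 by DESeq2 with the block) and the osteoclast-like against macrophage-like count 19.

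With each tumour left out, the counts ran over 0 to 891 for all cells, 547 to 1173 for stromal-like, 48 to 185 for macrophage-like, 91 to 3738 for osteoclast-like, 25 to 177 for T/NK-like, 15 to 801 for endothelial-like, 2 to 90 for CSF1, 32 to 35 for stromal-like against macrophage-like, 25 to 29 for osteoclast-like against macrophage-like and 14 to 23 for interaction. The count for all cells was 0 in edgeR without TGCT1, GCTB1 and GCTB2 (3417, 2873 and 2653 genes at an unadjusted p under 0.05). The numbers of gene lists past camera's threshold ran over 9 to 11 for all cells, 9 to 11 for stromal-like, 17 to 21 for macrophage-like, 10 to 15 for osteoclast-like, 12 to 14 for T/NK-like and 9 to 14 for endothelial-like; with an estimated correlation camera called 0 in each of the 6 comparisons (3, 5, 6, 5, 6 and 2 at an unadjusted p under 0.05), and fry called 1 for all cells, 9 for stromal-like, 9 for macrophage-like, 5 for osteoclast-like, 2 for T/NK-like and 2 for endothelial-like. Share differences (percentage points, TGCT minus GCTB) ran over -44.6 to -17.3 for stromal-like, 9.95 to 29.8 for macrophage-like, -3.36 to 1.1 for osteoclast-like, -4.5 to -1.18 for T/NK-like, 11.2 to 22.5 for endothelial-like, -5.92 to -3.08 for dendritic-like and 1.72 to 15.7 for mural-like.

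Among the named classes, share differences that turned were 1.1 for osteoclast-like cells without TGCT2, 1.33 for osteoclast-like cells with the unnamed osteoclast-scoring cluster (added), 0.633 for T/NK-like cells at 2000 UMIs per cell and 0.033 for T/NK-like cells with a minimum per library. The difference for unnamed cells turned from -7.86 to 6.64 without GCTB2 and to 9.13 with the stromal-scoring clusters counted as stromal-like (added). Dendritic-like cells had no cluster, and so no value, at 500 or 2000 UMIs, without doublet removal, at Leiden resolution 2 and with the automatic doublet threshold; with clusters made in each tumour they had none in TGCT1, TGCT2 and GCTB2.

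In macrophage-like sums the log2 fold change of IBSP turned with free RNA subtracted. It was 9.71 with the profile of barcodes of 10 to 100 UMIs and 9.66 with that of 100 to 500 UMIs (added). Neither value passed (edgeR adjusted p = 0.117 and 0.0903). In osteoclast-like sums, log2 fold changes turned without doublet removal C1QC (-0.15), CD74 (-0.31), CIITA (-0.046), COLEC12 (-1.12), CXCL2 (-1.13), FN1 (-0.052) and IRF8 (-1.22); with cells named by marker score GFPT2 (1.08) and UBE2C (-0.30); with the automatic doublet threshold (added) CD74 (-0.35), CIITA (-0.21), COLEC12 (-0.17) and CXCL2 (-0.71); with the unnamed osteoclast-scoring cluster (added) GFPT2 (0.85). In T/NK-like sums, log2 fold changes turned without doublet removal HMOX1 (0.73). Over the named genes, 3328 of 4041 values kept their direction and their side of the threshold, 531 lost the threshold, 120 gained it, 17 turned where either value passed and 45 turned where neither did; the cause was not tested.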

Other observations

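The mural marker test and the counts over other splits of the samples were chosen only after the result was seen; the other tests of this part were written before. IBSP and MMP13, genes of bone-forming cells, were lower in TGCT in the macrophage-like, T/NK-like and endothelial-like sums. Where these UMIs are RNA from other cells, their ratio should lie within 2-fold of that in the free RNA. The ratio of IBSP to MMP13 UMIs in these classes of both GCTB tumours deviated by at most 1.455-fold from that in barcodes of 100 to 500 UMIs of the same tumour (0.381 in GCTB1 and 1.74 in GCTB2). The ratio in the stromal-like cells themselves lay 1.79-fold and 1.34-fold away in GCTB1 and GCTB2. Free RNA of the stromal-like cells of GCTB may account for the difference in these classes; expression by the classes themselves, which would be a difference between the tumour types, was not tested and stays open.

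Cell cycle genes were higher in TGCT in the osteoclast-like sums. In the TGCT tumours, cells of this class with 2 or more cell cycle UMIs held 0.509, 0.232 and 0.566 of the osteoclast marker level of the other cells, against 0.809 and 0.874 in GCTB1 and GCTB2. At 2000 UMIs per cell, these cells were 44.2%, 64.5% and 60.6% of the class in TGCT1, TGCT2 and TGCT3. In GCTB1 and GCTB2 they were 40.8% and 43.4%. Having 2 such UMIs need not mean that a cell divides. Cells of another type among them predict such a lower level and may account for part of the rise. The macrophage marker level of these cells over the others was 1.08, 0.95 and 0.901 in TGCT1, TGCT2 and TGCT3. The median UMIs were 21700 against 21199, 25886 against 26948 and 31160 against 26507. Neither showed the rise in each tumour that macrophages or doublets would bring, so which cells these are stays open. Naming each cell by its highest marker score moved the median log2 fold change of the list from 2.29 to -0.064, with 0 of its genes past the threshold in edgeR and 0 at an unadjusted p under 0.05; how cells are assigned to classes thus stays open as the cause, and a difference in proliferation between the tumour types was not tested and stays open too.

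Between stromal-like TGCT cells with and without CSF1 UMIs 16 genes were named, 1 past the threshold and the others by unadjusted p. With 29, 81 and 58 pairs of cells matched on depth in TGCT1, TGCT2 and TGCT3, the median ratio of matched to unmatched log2 fold change was 0.807 (quartiles 0.676 to 0.902), where a difference in depth predicts under 0.5. Depth is thus not the whole cause for the 16 genes as a set, but DIO2 lay under 0.5, at 0.381. The pairs of TGCT2 still differed in depth, at medians of 21955 UMIs with and 18185 without CSF1. Whether mural cells sit among the cells without CSF1 stays open: the median log2 difference of 4 mural markers was 0.128, over values from -1.337 to 1.913 with an SD of 1.456, where mural cells predict -1 or lower. Both classes come from the same tumours, and no biological explanation was tested.

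Other splits of the 6 sums into groups of the same sizes were counted for the comparisons within TGCT. For stromal-like against macrophage-like cells 1 of 10 splits, the real one, gave as many ligand and receptor genes (34 against at most 0 in the others by edgeR). For osteoclast-like against macrophage-like cells it was 1 of 10 (30 against at most 0). For CSF1 it was 3 of 10 (1 against up to 8), and the splits that called more genes than the real one did not part the sums of every tumour. 10 splits are too few for a share under 0.05. In the 4 splits that part the sums of every tumour, the real one among them, the others gave at most 0 genes in edgeR in each of these comparisons.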
